A study of Saccharomyces cerevisiae
Saccharomyces paradoxus and Saccharomyces cerevisiae x Saccharomyces paradoxus with 12 samples.

How the data were processed

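MNase sequencing of nucleosome-sized DNA was analysed in 10 libraries of Saccharomyces cerevisiae, Saccharomyces paradoxus and their hybrid. The series lists 12 samples; the other 2 are control samples and were not analysed here. Per the labels' protocols, cells grown in rich medium were fixed with formaldehyde, spheroplasts were digested with MNase at a low and a high dose, the mononucleosomal band was isolated, similar amounts of DNA from 3 independent biological repeats were mixed, and libraries were sequenced on an Illumina instrument. Per the labels' titles, 6 libraries are parental pools (WT, htz1, isw1, gcn5, bre1 and rad6) that mix DNA of both species, and 4 are hybrids (WT, htz1, isw1 and gcn5), so each group has 1 library. The titles of the htz1, isw1 and gcn5 samples name 2 numbered preparations each and those of WT, bre1 and rad6 only 1, but each sample comes as a single file and was treated as 1 library.

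The deposited values are a smoothed read density, a signal without normalisation between libraries, given for 3751 genes and 2 genomes as 1900 positions each. No file header or label states the aligner, the genome build, the shift of reads or the smoothing. The start codon was taken to lie at position 1001, with 1000 bp upstream and 900 bp downstream. An isolated read adds the same area of 0.914518 in every library, and 86 of 87 isolated bumps (98.9%) held a whole number of such areas within 0.02 reads, so areas were divided by this value to give estimated reads. They are estimates rather than counted reads, neighbouring genes share reads, and duplicate reads cannot be told from independent molecules. Of the 3751 genes, 3744 matched the R64 assembly, which was used for names, coding lengths and gene order only, and 7 did not. The values of 1 gene, PFA3, were missing for S. paradoxus in bre1 and rad6. Density is given relative to the mean of the genome in that library.

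Estimated reads over both genomes were 2498393 in the WT pool, 6697914 in htz1, 7455845 in isw1, 5073161 in gcn5, 4146356 in bre1 and 3131483 in rad6, and 2452206, 9313471, 7572286 and 5536923 in the WT, htz1, isw1 and gcn5 hybrids. The S. paradoxus share ran from 27.9% in the gcn5 pool to 67.6% in the isw1 hybrid. With a median of 14.8 to 84.3 reads per S. cerevisiae promoter window, counting error alone limited the precision of single windows in the WT pool.

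The promoter window was the 200 bp upstream of the start codon. Of 3744 such windows 554 overlap the window of another measured gene. Estimated reads were scaled to the total of each genome in each library (common scale of 2693903), windows with a mean under 10 reads were left out, and log2(scaled reads + 4) was tested with limma 3.58.1 (trend and robust options, statmod 1.5.0) in R 4.3.3 with Benjamini-Hochberg adjustment at 0.05. Changes are on this log2 scale, which understates changes at low values. Mutants were compared with WT over the 10 libraries of one genome with background as an additive term, leaving 3 residual degrees of freedom. The htz1, isw1 and gcn5 effects rest on 2 libraries against 2, those of bre1 and rad6 on 1 parental library that was assumed to vary like the others. Hybrids were compared with pools over 8 libraries with genotype as a block (3 residual degrees of freedom), and species or alleles with the pool or library as a block (5 and 3). The pairing comes from the titles for genotype and from sharing one library for genomes. Whether the species difference differed between pools and hybrids was tested as an interaction over the 8 libraries (6 residual degrees of freedom) with the library as a block and no pairing by genotype, signed as the hybrid difference minus the parental one. The planned design assumed counts and a count test; the density needed limma instead.

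Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, over 278 tests. The Benjamini-Hochberg adjustment was made over the lists of each comparison separately, and not over all 278 tests. The 20 lists were mating and haploid state (22 measured genes), stress response (27), galactose (9), phosphate (12), histones (7), glycolysis (13), hexose transport (7), amino acid synthesis (41), respiration (33), proteasome (26), cell cycle (29), meiosis and sporulation (24), ribosome biogenesis (43), cell wall (18), ergosterol (21), silencing (2), chromatin remodelling (23), ribosomal proteins (65), mitochondrial ribosome (51) and chromosome ends (78). The silencing list had fewer than the 5 genes needed and was not tested. Chromosome ends were the 10 outermost annotated genes of each end. Sequence lists were not run, because the gene annotation used here came without the genome sequence. With the preset correlation 12 tests passed and with the estimated one 0, whose smallest adjusted p was 0.454 by camera.

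Genes named in the text followed a rule. Among passing windows with a mean of at least 20 reads and the same sign in every background or pair, the 10 largest rises and the 10 largest falls were eligible. Where fewer than 5 passed in a direction the 5 smallest p were eligible, as were the 3 members with the smallest p of each passing list, the deleted genes, the markers and HO. The comparisons, window, test thresholds, lists and naming rule were chosen before the data were examined, except for limma itself, its pseudocount and the chromosome-end definition, which the form of the data required. MET17, the genes at steps along chromosomes, genes empty in other libraries and the mating genes in 100 bp windows were chosen after their values were seen. The 10 windows of 100 bp per gene ran from 400 bp upstream to 600 bp downstream of the start codon.

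Average profiles were smoothed with an SD of 20 bp in numpy 2.4.6 and scipy 1.17.1 (python 3.11.15) and aligned on the first nucleosome downstream of the promoter, called from all libraries together. Spacing is the slope of peak position on peak number over 5 nucleosomes in 2132 S. cerevisiae and 2263 S. paradoxus genes with coding sequences of at least 900 bp. Depletion is the log2 ratio of mean density in the promoter window to that in the gene body. Both are values per library without a test. Figures were drawn with matplotlib 3.10.9.

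The procedures were tested on simulated data with known answers. In the htz1 comparison 15% of 2-fold and 1% of 1.5-fold changes were recovered over 3628 genes, and in the bre1 comparison 3% and 1%. Simulated values held counting error on top of a spread close to the median residual SD of these comparisons, 0.255. That residual SD already includes counting error, so recovery in them may be understated. Recovery was 82% and 16% for hybrids against pools over 3662 genes, 91% and 42% for the species over 3602, and 26% and 4% for the interaction over 3687. At most 0.329% of unchanged windows were called. Spacing was recovered within 0.3 bp over 2000 genes.

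Alternatives were other window widths, scalings, pseudocounts, filters and thresholds, the promoter relative to the gene body, fits without the block, fits without each library, other alignments and smoothing of profiles, and a correlation estimated for lists. No group has the 4 samples that a test for outlying samples would need.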

Results

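Nucleosome-sized DNA was measured in the budding yeast Saccharomyces cerevisiae, in its close relative Saccharomyces paradoxus and in the hybrid of both, in wild type (WT) and in strains lacking a chromatin regulator. HTZ1 encodes the histone variant that is placed beside promoters. ISW1 encodes the ATPase of remodelling complexes that slide and space nucleosomes. GCN5 encodes a histone acetyltransferase that works as a transcriptional coactivator. BRE1 and RAD6 encode the ligase and the conjugating enzyme that together attach ubiquitin to a core histone. The series compares nucleosome positions between species, between the alleles of a hybrid nucleus, and between WT and these deletions. The 10 libraries analysed were 6 parental pools, each a mix of DNA from both species, and 4 hybrids (WT, htz1, isw1 and gcn5), with 1 library per group made from 3 mixed biological repeats. Estimated reads around the start codons of 3751 genes ranged from 2452206 in the WT hybrid and 2498393 in the WT pool to 9313471 in the htz1 hybrid. The median promoter window held 14.8 estimated reads for the S. cerevisiae genome of the WT pool and 84.3 for that of the htz1 hybrid.

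The deleted genes were looked at first. ISW1, GCN5 and RAD6 are nonessential, so their coding sequences can be removed whole. Inside ISW1, the isw1 pool held 0.185% of the mean density of the S. cerevisiae genome and 8.83% of that of S. paradoxus, and the isw1 hybrid −0.0251% and 2.98%, against 55.7% to 123% elsewhere. Inside GCN5, the gcn5 libraries held at most 0.719%, against 39.7% to 72.5% in the others. RAD6 held −0.102% and −0.0151% in the rad6 pool, against 29.3% to 81.1%. HTZ1 and BRE1 were not among the genes of the table, so the htz1 and bre1 labels stayed unchecked, as did the markers LEU2, URA3, HIS3 and LYS2. HO, the endonuclease gene that drives mating-type switching, was empty in the S. paradoxus genome of all 10 libraries, whose labels name an ho deletion. In the S. cerevisiae genome HO was empty in the WT hybrid (−0.00613%) and at 61.8% to 135% in the others.

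Nucleosome spacing inside genes was compared first, because ISW1 is a spacing enzyme. In WT, the nucleosomes counted from the first one after the promoter lay 163.5 to 164.5 bp apart. Loss of ISW1 brought them closer together, by −4.0 bp on average (SD 0.61, n = 4 values, 2 genomes in each of 2 libraries), with −4.4 and −3.3 bp in the pool and −3.7 and −4.6 bp in the hybrid. The outermost of the 5 nucleosomes lay at 641.25 bp in isw1 and at 657.5 bp in WT. Loss of HTZ1 widened the spacing by 2.03 bp (SD 0.33) and loss of GCN5 by 1.53 bp (SD 0.17), each in 4 of 4 values. The bre1 and rad6 pools differed by 0.15 bp (SD 0.78) and −0.6 bp (SD 0.42) over n = 2 values. The ratio of peak to trough at the fourth nucleosome was 1.46 in isw1 and 2.17 in WT, a difference of −0.707 (SD 0.0557), while htz1 gained 0.311. Bre1 and rad6 lay below WT by −0.304 and −0.303. With spacing read from the autocorrelation of coding sequences instead, the isw1 difference turned to 1.75 bp, and htz1 and gcn5 stood at 2.5 and 2.75 bp. Genomes of one library are not independent samples, so an SD over n = 4 values rests on 2 mutant libraries and one over n = 2 on a single library. These differences had no test.

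**Figure D1:**
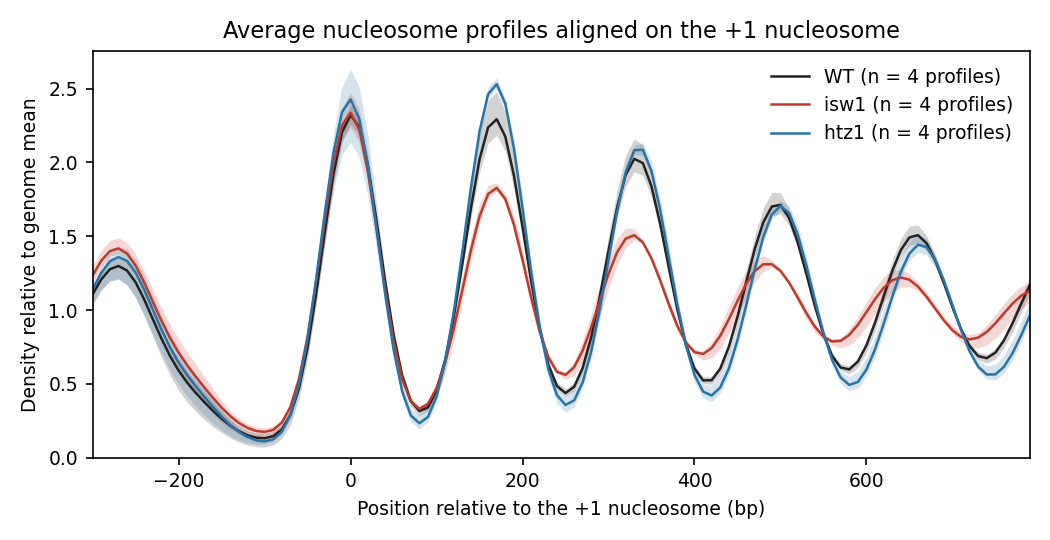
Average nucleosome density relative to the mean, against the distance in bp from the first nucleosome of the gene, for WT, isw1 and htz1. Lines are means of n = 4 profiles (parental pool and hybrid, both genomes), bands run from the lowest to the highest, and the isw1 peaks fall short of the WT peaks by a growing distance, 641.25 against 657.5 bp for the last of 5.

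Promoters of yeast genes are depleted of nucleosomes, which leaves the DNA open to transcription factors. In WT the log2 ratio of promoter to gene-body density was −1.11 and −0.72 for the S. cerevisiae and S. paradoxus genomes of the pool and −0.75 and −0.71 for those of the hybrid. Isw1 lay above WT, by 0.18 on the log2 scale (SD 0.12, n = 4 values from 2 libraries), with 0.32, 0.23, 0.07 and 0.09 in the separate values. The lowest point of its average profile upstream of the first nucleosome rose to 0.218 from 0.169. The ratio differed by 0.06 (SD 0.06) in htz1 and by −0.01 (SD 0.18) in gcn5. In gcn5 1 value lay above WT, at 0.23 in the S. paradoxus genome of the pool, and 3 below. Bre1 and rad6 moved it by 0.10 (SD 0.14) and −0.07 (SD 0.30) over n = 2 values, the genomes of 1 library each. No test was made of these differences, and the SD is not over independent samples. The WT pool and hybrid, at −1.11 and −0.75 in S. cerevisiae, lay further apart than isw1 and WT.

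**Figure D2:**
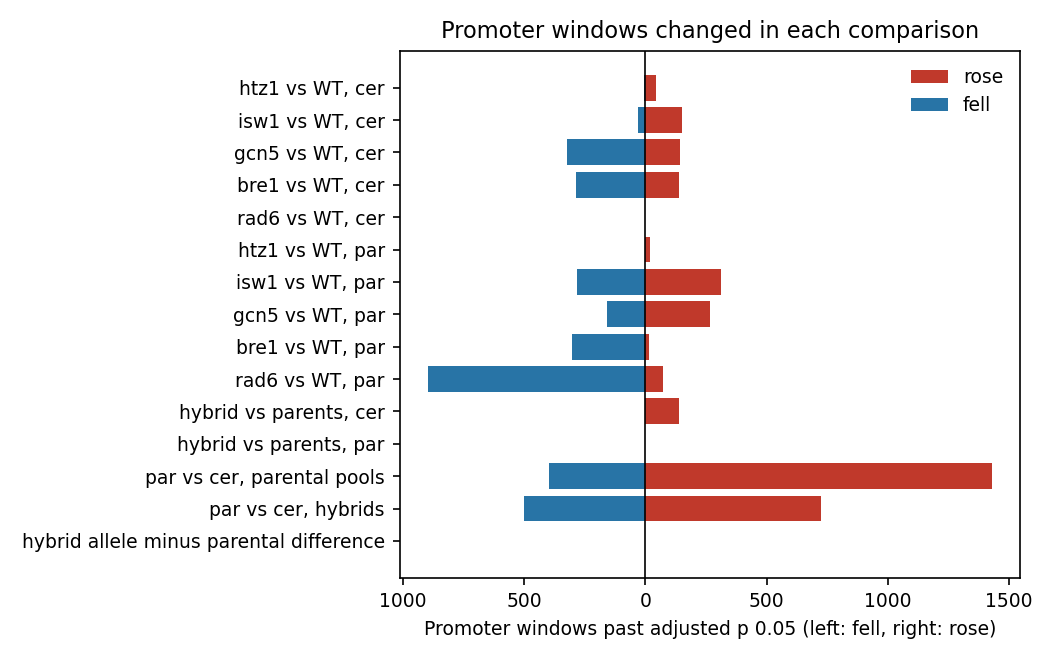
Number of promoter windows past adjusted p 0.05 (limma) in the 15 comparisons, with windows that rose drawn to the right and windows that fell to the left. The longest bar is that of the species in the pools, where 1429 windows were higher in S. paradoxus and 399 lower. Among the mutants it is that of rad6 in the S. paradoxus genome, where 897 fell and 74 rose.

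Among the few promoters that gained nucleosome density without the histone variant HTZ1 were those of some ribosomal protein genes, which are among the most transcribed genes of growing yeast. In the S. cerevisiae genome RPL25, a protein of the large ribosomal subunit, rose by 1.48 ± 0.30 (log2, SE; limma, adjusted p 0.0077), and RPS0A, of the small subunit, by 1.17 ± 0.22 (adjusted p 0.0054). RPL16B rose by 1.42 and MRPL15, a mitochondrial ribosomal protein, by 1.44. The rise was largest at the uncharacterised gene YMR265C, at 2.11 ± 0.32 (adjusted p 0.00095), and UTH1, a cell wall and mitochondrial protein, rose by 1.88. Density fell at TRP4, an enzyme of tryptophan synthesis, by −1.11 ± 0.29 (adjusted p 0.043), at the vacuolar casein kinase gene YCK3 by −1.09 ± 0.26 (adjusted p 0.026) and at the haem transporter gene PUG1 by −1.02. Relative to 41 neighbouring genes 30 windows rose and 2 fell there, and UTH1, MRPL15, RPL16B, TRP4 and PUG1 no longer passed, at 1.77, 1.51, 1.43, −0.97 and −1.03 (limma, adjusted p 0.0533 to 0.0996). In the S. paradoxus genome RPL25 rose by 1.58 ± 0.27 (adjusted p 0.00094), RPP2A, a protein of the ribosomal stalk, by 1.09 ± 0.26, and VRG4, a Golgi transporter of nucleotide sugars, by 1.09 ± 0.23 (adjusted p 0.016). RPL25 and RPP2A lie on chromosome XV, where the S. paradoxus signal of the htz1 hybrid was raised 1.42-fold as a whole. Relative to 41 neighbouring genes RPL25 rose by 1.33 (limma, adjusted p 0.0138) and VRG4 by 1.11, while RPP2A did not pass, at 0.89 (adjusted p 0.0987). THI6, of thiamine synthesis, fell by −0.93 (adjusted p 0.048), while MAK10 and SEC28 did not pass, at −0.92 and −0.83. The S. cerevisiae genes named here, and RPL25, RPP2A and VRG4 in S. paradoxus, passed in the same direction in 3 or more mutants. All were measured against the same WT libraries, so these changes are not particular to htz1.

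Of 3628 promoter windows tested in S. cerevisiae, 46 rose and 5 fell in htz1, and of 3634 in S. paradoxus 21 rose and 3 fell. Ribosomal protein genes stood above the other genes in both genomes. Of 64 members in S. cerevisiae 10 rose and 0 fell (17 and 1 adjusted over the list alone; 492 of all windows had an unadjusted p under 0.05 in limma), with a median of 0.52 against −0.05 for the other genes (camera, adjusted p 4.78e-10; adjusted p = 0.972 with an estimated correlation). Of 63 in S. paradoxus 4 rose and 0 fell (19 and 1 adjusted over the list alone; 490 of all windows had an unadjusted p under 0.05), with a median of 0.41 against 0.03 (camera, adjusted p 3.32e-08; adjusted p = 0.959 with an estimated correlation). Scaled by median ratios, 20 windows rose and 1 fell in S. cerevisiae, and 0 rose and 2 fell in S. paradoxus by limma. In S. cerevisiae 112 windows passed without the WT pool, 32 without the WT hybrid and 0 by limma without either htz1 library (285 and 262 at an unadjusted p under 0.05); in S. paradoxus 189 and 49 passed without the WT pool and hybrid, 14 and 1 without the htz1 pool and hybrid, 12 without either isw1 library, and 160 and 164 without the gcn5 pool and hybrid.

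Ribosomal protein promoters were among those that gained density without the ISW1 remodeller. Several changes named here passed in the same direction in 3 or more mutants, all against the same WT libraries. They are not particular to isw1, and were RPL16B and DAL1 in S. cerevisiae, and MET28, RPS17B, SSA4 and PTC1 in S. paradoxus. Against the mean of the other mutants, 2 S. cerevisiae and 269 S. paradoxus windows passed in limma, where 179 and 595 passed against WT. RPL16B, a protein of the large subunit, rose by 2.05 ± 0.34 in the S. cerevisiae genome (limma, adjusted p 0.00063), and AAT2, an aspartate aminotransferase, by 2.52 ± 0.32 (adjusted p 2.9e-05). Among the falls were MNN11, a Golgi mannosyltransferase gene, by −1.58 ± 0.23 (adjusted p 7.2e-05), DAL1, the allantoinase gene of nitrogen scavenging, by −1.27 ± 0.29 (adjusted p 0.01), and SSK2, a kinase of the osmotic stress pathway, by −1.18. UGA3, the activator of genes for GABA use, rose in the S. paradoxus genome by 1.95 ± 0.30, the sulfur regulator MET28 by 1.70 ± 0.26 (adjusted p 1.2e-05) and RPS17B by 1.64 ± 0.24. SSA4, a heat-induced chaperone gene, fell by −2.11 ± 0.26 (adjusted p 4.6e-07), as did CET1, a subunit of the mRNA capping enzyme, by −1.97, and the phosphatase gene PTC1, by −1.77.

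Some genes of mating and the haploid state, most of which are shut in one cell type or another, lost density in isw1 in the S. paradoxus genome. There AXL1, a protease that matures a pheromone, fell by −1.51 ± 0.29 (limma, adjusted p 0.00031), the pheromone receptor gene STE2 by −1.33 ± 0.29 (adjusted p 0.0012) and FIG1, of cell fusion, by −1.19 ± 0.27 (adjusted p 0.002). As a list, 6 of 22 mating genes fell and 0 rose (6 and 0 adjusted over the list alone; 1081 of all windows had an unadjusted p under 0.05), with a median of −0.45 against 0.04 (camera, adjusted p 0.000783; adjusted p = 0.454 with an estimated correlation). In S. cerevisiae their median was −0.26 against 0.12 (camera, adjusted p 0.00856; adjusted p = 0.934 with an estimated correlation), and 0 of 22 passed by limma (0 adjusted over the list alone; 713 of all windows had an unadjusted p under 0.05). STE12, the pheromone-response activator, stood at −0.89 (adjusted p 0.069), FIG2 at −1.07 (adjusted p 0.089) and HO at −0.71 (adjusted p 0.12). In S. paradoxus AXL1, STE2 and FIG1 fell in 3 or more mutants, so their fall is not particular to isw1. AXL1 density there was 0.109 and 0.135 in the isw1 pool and hybrid, 0.0707 in bre1 and 0.115 in rad6. In the WT pool and hybrid it was 0.514 and 0.379.

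Counted over the genome, 150 windows rose and 29 fell in S. cerevisiae in isw1, and 313 rose and 282 fell in S. paradoxus. Ribosomal protein genes had 26 of 64 risen and 0 fallen in S. cerevisiae (36 and 2 adjusted over the list alone), at a median of 0.96 against 0.11 (camera, adjusted p 4.24e-13; adjusted p = 0.862 with an estimated correlation). In S. paradoxus 35 of 63 rose and 2 fell (40 and 2 adjusted over the list alone), at a median of 0.90 against 0.03 (camera, adjusted p 4.17e-15; adjusted p = 0.454 with an estimated correlation). Median-ratio scaling gave 73 rises and 39 falls in S. cerevisiae, where the median of all windows was 0.11, and 302 and 324 in S. paradoxus. In S. cerevisiae 85 windows passed without either htz1 library, 80 without the isw1 pool and 75 without the isw1 hybrid, and in S. paradoxus 87 and 281 without the isw1 pool and hybrid.

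Loss of the GCN5 acetyltransferase changed 466 of 3628 promoter windows (12.8%) in the S. cerevisiae genome. NOP1, the methyltransferase of ribosomal RNA, rose by 1.58 ± 0.36 (limma, adjusted p 0.0048), and RRP9, of the same small nucleolar particles, by 1.40 (adjusted p 0.027). RPL5 rose by 1.96 (adjusted p 0.0019), while RPS29A fell by −1.19 (adjusted p 0.0034) and UTP5, of small-subunit assembly, by −1.09 (adjusted p 0.022). RGS2, a brake on glucose signalling through cAMP, rose by 1.88 ± 0.24 (adjusted p 1.7e-05), DIG1, an inhibitor of the mating activator STE12, by 1.89 ± 0.30 and RPA190, the largest subunit of RNA polymerase I, by 1.56. DAL7, a malate synthase of allantoin breakdown, fell by −1.54 ± 0.24 (adjusted p 0.00025), and CAF4, of mitochondrial fission, by −1.54 ± 0.26. The chloride channel gene GEF1 fell by −1.39 and the checkpoint gene RAD24 by −1.31. RPL5, RGS2 and DIG1 rose in 3 or more mutants against the same WT libraries, as did RPP2A in S. paradoxus. These rises are not particular to gcn5. In the S. paradoxus genome RPP2A rose by 1.70 ± 0.26 (adjusted p 5.4e-05), RPL36B by 1.62 ± 0.25 and CAR2, an enzyme of arginine breakdown, by 1.42 ± 0.24 (adjusted p 0.00023). COX4, a subunit of cytochrome c oxidase, fell by −1.58 ± 0.24 (adjusted p 4.7e-05), and the cell-cycle activator gene SWI5 by −1.15 ± 0.23 (adjusted p 0.0012).

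RGS2, DIG1, RPL5, RRP9 and RPA190 lie on chromosomes XV and XVI, where the S. cerevisiae signal of the gcn5 hybrid was raised as a whole. That signal stepped up between MGR3 and ASC1 on chromosome XIII, by 1.52-fold, and between ABZ1 and ARC35 on chromosome XIV, to 2.12-fold. Chromosomes XV and XVI stood 1.94-fold and 1.98-fold above their level in the other libraries. Relative to 41 neighbouring genes, DIG1 rose by 1.52, RGS2 by 1.49, SUI3, a translation initiation factor gene on chromosome XVI, by 1.02, and RPL5 by 1.61 (limma, adjusted p 0.00845). RPA190, at 1.09 (adjusted p 0.054), and RRP9, at 0.99 (adjusted p 0.165), no longer passed. NOP1 lies outside the raised part. Before the first step 83 of 2676 windows rose and 278 fell, and beyond it 61 of 951 rose and 43 fell.

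**Figure D3:**
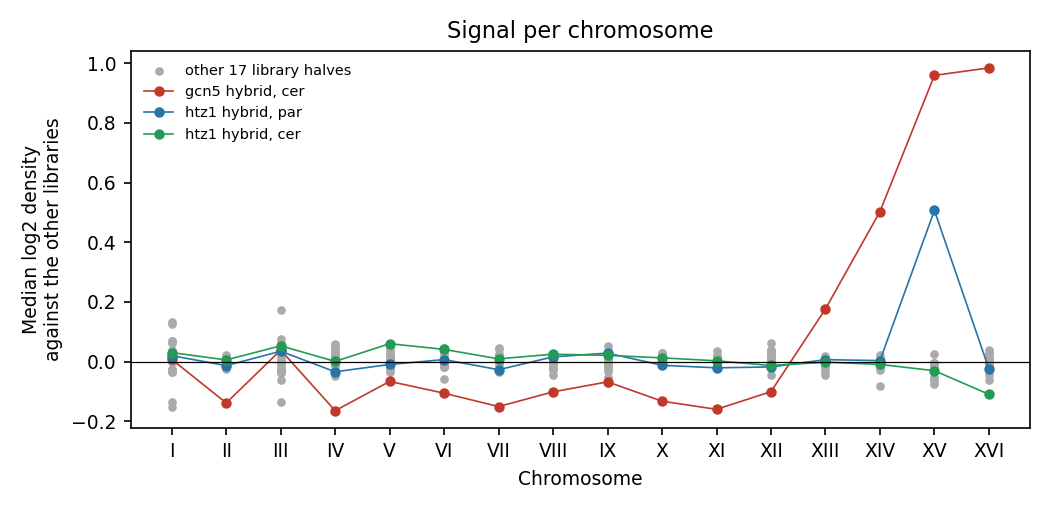
Median log2 signal of each chromosome against the other libraries, per library and genome. The S. cerevisiae genome of the gcn5 hybrid (red) reaches 0.50 on chromosome XIV, 0.96 on XV and 0.98 on XVI, the S. paradoxus genome of the htz1 hybrid (blue) reaches 0.51 on XV, and all other values shift by at most 0.18.

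In all, 145 windows rose and 321 fell in S. cerevisiae in gcn5, and 266 rose and 159 fell in S. paradoxus. Ribosomal protein genes had 8 of 64 risen and 1 fallen in S. cerevisiae (8 and 2 adjusted over the list alone; 1044 of all windows had an unadjusted p under 0.05), at a median of 0.32 against −0.14 (camera, adjusted p 1.52e-05; adjusted p = 0.992 with an estimated correlation). In S. paradoxus 23 of 63 rose and 0 fell (32 and 3 adjusted over the list alone; 1012 of all windows had an unadjusted p under 0.05 in limma), at a median of 0.59 against −0.00 (camera, adjusted p 1.42e-08; adjusted p = 0.954 with an estimated correlation). Ribosome biogenesis genes, which assemble the subunits, had 2 of 42 risen and 1 fallen in S. cerevisiae (2 and 1 adjusted over the list alone), at a median of 0.27 against −0.14 (camera, adjusted p 0.025; adjusted p = 0.992 with an estimated correlation). These S. cerevisiae counts include the raised chromosomes. Relative to 41 neighbouring genes 5 ribosomal protein genes rose and 1 fell, at a median of 0.34 against −0.19, and 1 biogenesis gene rose and 1 fell, at 0.21 against −0.19. The median of all S. cerevisiae windows was −0.13, and median-ratio scaling gave 208 rises and 156 falls there. In S. cerevisiae 258, 304, 235 and 250 windows passed without the htz1 pool, the gcn5 pool, the WT hybrid and the htz1 hybrid, and 15 without the gcn5 hybrid; in S. paradoxus 667 and 270 passed without the WT pool and hybrid and 190 without the gcn5 hybrid.

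A set of promoters was emptied in the parental pool that lacks the ubiquitin ligase BRE1, the only bre1 library. The S. paradoxus genes named here, and RPS0A in S. cerevisiae, passed in the same direction in 3 or more mutants. All were measured against the same WT libraries, so these changes are not particular to bre1. In the S. cerevisiae genome YSP2, of sterol transport, fell by −3.21 ± 0.37 (limma, adjusted p 2.6e-06), CBP4, an assembly factor of the respiratory chain, by −3.03 ± 0.47 (adjusted p 0.00036) and RPS25A, of the small ribosomal subunit, by −2.71 ± 0.43 (adjusted p 0.00043). The phosphate transporter gene PHO89 fell by −2.36 ± 0.39, mitochondrial malate dehydrogenase MDH1 by −2.53 and the kinase gene MKK2 by −2.32. AAT2 rose by 2.45 and RPS0A by 1.75 ± 0.28. MMS2, which acts in ubiquitin-dependent DNA repair, fell in the S. paradoxus genome by −2.52 ± 0.33 (adjusted p 1.5e-06), as did RHO1, a GTPase of cell wall synthesis, by −2.37 ± 0.33 (adjusted p 5e-06), the repressor gene NRG1, by −2.41, and the spindle checkpoint gene MAD1, by −2.33. Rises there were smaller, with GPI19, of lipid anchor synthesis, at 1.45 ± 0.30 (adjusted p 0.00081) and the histone chaperone gene NAP1 at 1.05 ± 0.31 (adjusted p 0.021).

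The bre1 counts were 140 rises and 286 falls in S. cerevisiae and 15 rises and 301 falls in S. paradoxus. Ribosomal protein genes had 21 of 64 risen and 3 fallen in S. cerevisiae (28 and 4 adjusted over the list alone; 995 of all windows had an unadjusted p under 0.05), at a median of 0.80 against 0.00 (camera, adjusted p 2.09e-06; adjusted p = 0.964 with an estimated correlation). A single library carried each mutant effect and was assumed to vary like the others. Densities of MMS2 and MAD1 in S. paradoxus nearly matched, at 0.111 and 0.114 in bre1 and 0.872 and 0.793 in the WT pool. They may therefore not be separate changes. In S. cerevisiae 282, 283 and 271 windows passed without the htz1 pool, the gcn5 pool and the htz1 hybrid.

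Loss of RAD6, the partner enzyme of BRE1, lowered many promoters in the S. paradoxus genome of its only library, and its effect differed between the genomes at 53 windows (limma), at 14 with median-ratio scaling and at 159 relative to 41 neighbouring genes. ERT1, an activator of genes for growth without glucose, fell by −2.99 ± 0.33 (limma, adjusted p 3.1e-08), the autophagy gene ATG3 by −2.80 ± 0.30 (adjusted p 2.8e-08), and MMS2 by −2.49 ± 0.33 (adjusted p 1.8e-06). MAD1 fell by −2.32 and MDH1 by −2.27. Densities of MMS2 and MAD1 in S. paradoxus nearly matched, at 0.115 and 0.116 in rad6 and 0.872 and 0.793 in the WT pool. They may therefore not be separate changes. ERT1, MMS2 and MAD1 fell in 3 or more mutants, and NAP1 and GLN3, named next, rose in 3 or more. All were measured against the same WT libraries, so these changes are not particular to rad6. PDX1, of the pyruvate dehydrogenase complex, rose by 1.98 ± 0.28 (adjusted p 5.3e-06), NAP1 by 1.65 ± 0.31 (adjusted p 0.00019) and GLN3, the activator of nitrogen genes, by 1.61 ± 0.29 (adjusted p 0.00014). There 74 windows rose and 897 fell around a median of −0.42, and 273 rose and 335 fell under median-ratio scaling, where ERT1 and ATG3 stood at −2.73 and −2.44. In the S. cerevisiae genome 0 of 3628 windows passed by limma, with 424 at an unadjusted p under 0.05 where 181 were due by chance. The smallest adjusted p values there were those of RGS2 at 1.46 (adjusted p 0.062), of the haem gene HEM13 at 1.26 and the linker histone gene HHO1 at 1.24 (adjusted p 0.075 each), and of YCK3 at −1.61 (adjusted p 0.062). ATG3 and CBP4 stood at −2.02 and −1.99 (adjusted p 0.075 each). Without the WT pool, the WT hybrid, the isw1 pool and the isw1 hybrid, 52, 14, 10 and 11 S. cerevisiae windows passed.

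Some ribosomal protein promoters rose in several mutants, all measured against the same pair of WT libraries, and each of these list calls was lost with an estimated correlation (camera, adjusted p = 0.454 or more with an estimated correlation). Of the members, 17 in each genome were among 58 genes with positions that parted WT from the mutants. Such positions were empty in both WT libraries and filled in every mutant, or the reverse. Without these genes, 6, 17, 5 and 14 of 47 rose in htz1, isw1, gcn5 and bre1 in S. cerevisiae, at medians of 0.49, 0.96, 0.33 and 0.75, and 3, 24 and 15 of 46 rose in htz1, isw1 and gcn5 in S. paradoxus, at medians of 0.35, 0.82 and 0.58. The other comparisons showed no such rise. In S. paradoxus 1 of 46 rose in bre1, at a median of −0.14 against −0.10 for other genes. In rad6 0 of 46 rose there and 10 fell, at −0.29 against −0.42, and 0 of 47 rose in S. cerevisiae. Mutants that share no library with each other, a parental pool of one and a hybrid of another, correlated across genes at a mean r of 0.235 in S. cerevisiae and 0.293 in S. paradoxus, against 0.373 and 0.447 for the same mutant. For htz1 alone it was 0.305 and 0.269, which lay between the values of the htz1 pool with the gcn5 hybrid, 0.227 and 0.220, and with the isw1 hybrid, 0.336 in both genomes. The bre1 pool correlated with the isw1 hybrid at 0.493 and 0.460. Genes are not independent replicates, and no p is given. Measured against the mean of the other mutants, a reference chosen after the data were examined, 1, 2, 608, 125 and 1 windows passed in S. cerevisiae for htz1, isw1, gcn5, bre1 and rad6, and 248, 269, 434, 131 and 853 in S. paradoxus (limma). Of the 248 for htz1 only 1 was among its 24 windows against WT, and the htz1 effects on the different references correlated at r 0.0601 there. Against WT, 46 windows rose and 9 fell in 3 or more mutants in S. cerevisiae, and 45 rose and 150 fell in S. paradoxus.

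The hybrid was compared with the parental pools to see whether a genome is packaged differently when it shares a nucleus with another. In the S. cerevisiae genome some ribosomal protein promoters gained density in the hybrid, in a count that hung on the processing. RPS6A rose by 1.17 ± 0.21 (limma, adjusted p 0.0074), RPS17B by 1.04 and RPS0A by 0.80 ± 0.16 (adjusted p 0.011), each in 4 of 4 genotypes. RPS6A lies on chromosome XVI, raised in the gcn5 hybrid, and relative to 41 neighbouring genes it rose by 0.94 (adjusted p 0.0301). AAT2 rose by 1.72 ± 0.23 (adjusted p 0.0011) and UGA3 by 1.28 ± 0.24 (adjusted p 0.0078), also in 4 of 4. ISC1, a sphingolipid hydrolase gene, fell by −0.59 ± 0.17 (adjusted p 0.045; 3 of 4 genotypes) and did not pass relative to neighbours (adjusted p 0.0868). Of 3662 windows 138 rose and 1 fell, and of 64 ribosomal protein genes 23 rose and 0 fell (31 and 2 adjusted over the list alone; 802 of all windows had an unadjusted p under 0.05), at a median of 0.54 against 0.22 (camera, adjusted p 0.000127; adjusted p = 0.984 with an estimated correlation). Relative to the median of all windows, 0.22, median-ratio scaling left 1 rise and 0 falls. A window of 150 bp gave 3 changed windows, scaling by neighbours 66, and a fit without the genotype block 0 by limma (400 at an unadjusted p under 0.05). Without the WT, htz1, isw1 and gcn5 pairs 47, 1, 298 and 0 windows passed.

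In the S. paradoxus genome 0 of 3669 windows passed by limma between hybrids and pools, and 393 had an unadjusted p under 0.05. MF(ALPHA)1, a gene of the alpha pheromone, stood at 0.83 ± 0.19 (adjusted p 0.14), the cell wall gene SCW10 at 0.59 (adjusted p 0.28), SAP1 at −0.80 ± 0.17 (adjusted p 0.11) and the meiotic chromosome gene RED1 at −0.81 (adjusted p 0.23), each with the same sign in 4 of 4 genotypes. Without the WT, htz1 and gcn5 pairs 17, 1 and 1 windows passed.

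Mating genes changed between hybrids and pools in windows of 100 bp around the start codon, a finer view chosen after the data were examined. Haploid cells of mating type a express the a-specific genes, cells of type alpha the alpha-specific ones, and a diploid hybrid shuts both along with the haploid-specific genes. The labels give the parental S. cerevisiae strain as a diploid and the S. paradoxus strain as haploid of type alpha. In the S. cerevisiae genome windows passed at the a-specific genes AGA2 (1.30, adjusted p 0.024), STE2 (1.01) and BAR1 (1.26, adjusted p 0.0485), in limma. In the S. paradoxus genome they passed at the alpha-specific genes MF(ALPHA)1 (1.28, adjusted p 0.0014), STE3 (1.10) and MF(ALPHA)2 (−0.97, adjusted p 0.0313). The window that passed at MF(ALPHA)2 fell, beside others of this gene at up to 0.79 that did not pass, and those at the other 5 genes rose. ASG7, a further a-specific gene, did not pass in either genome (smallest adjusted p 0.211 in S. cerevisiae). Of 7 haploid-specific genes 4 had a changed window in both genomes, STE4, GPA1, FUS3 and AXL1. STE4 stood at 1.58 (adjusted p 0.0203) in S. cerevisiae and 1.66 ± 0.19 (adjusted p 0.00029) in S. paradoxus, and GPA1 fell in a different window of each, at −1.09 (adjusted p 0.0177) from the start codon on and at −1.07 (adjusted p 0.00295) from 200 bp downstream on. PRM1, STE4 and AXL1 lie on chromosomes XIV, XV and XVI, whose S. cerevisiae signal was raised in the gcn5 hybrid, and these windows were not scaled by neighbours. Of 22 mating genes 9 had a changed window in S. cerevisiae, against 172 of 3724 other genes (Fisher's exact test, one-sided p 3.4e-07), and before the raised part 6 of 18 against 123 of 2742 (exact one-sided p 0.000108). In S. paradoxus 7 of 22 had one, against 6 of 3721 (exact one-sided p 1.41e-13). As a preset list over promoter windows, mating genes did not pass camera between hybrids and pools in either genome.

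Between the species, 1828 of 3602 promoter windows (50.7%) differed in the pools. SNO2 and SNZ2, neighbours that act in pyridoxine synthesis, stood higher in S. paradoxus by 4.29 ± 0.18 (limma, adjusted p 4.3e-15) and 3.85 ± 0.16. Both have near-identical copies elsewhere in the genome, so the assignment of their reads is uncertain. RAD26, a repair ATPase of transcribed genes, was higher by 2.90 ± 0.24 (adjusted p 2.3e-09), TIP20, of vesicle transport, by 3.13 ± 0.24 (adjusted p 6.3e-10) and PXL1, of polarised growth, by 2.98. RNH202, a subunit of ribonuclease H, was lower by −2.81 ± 0.26 (adjusted p 1.1e-08), the oxidoreductase gene OYE3 by −2.69 ± 0.26 (adjusted p 1.9e-08), MTR3, of the exosome, by −2.43 and the repressor gene SFL1 by −1.90 ± 0.20 (adjusted p 8e-08). Each kept its direction in 6 of 6 pools. Of the windows that differed, 1429 were higher in S. paradoxus and 399 lower. Around a median of 0.31, median-ratio scaling split them into 894 and 904.

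The alleles of the hybrid, which share one set of transcription factors, differed at many of these promoters. SNO2 and SNZ2 stood at 4.01 ± 0.19 (limma, adjusted p 2e-12) and 3.38 ± 0.17, RAD26 at 2.52 ± 0.21 (adjusted p 3e-08), PXL1 at 2.57 and TIP20 at 2.17 ± 0.23 (adjusted p 1.3e-06). RNH202 stood at −2.90 ± 0.30 (adjusted p 4e-06), OYE3 at −2.44 ± 0.18 (adjusted p 3.9e-09), SFL1 at −1.96 ± 0.18 (adjusted p 1e-07) and the glutaredoxin gene GRX1 at −1.93, all in 4 of 4 hybrids. Of 3706 windows 725 were higher on the S. paradoxus allele and 501 lower. Over the 3602 windows tested in both, the differences between species and between alleles correlated at r 0.880 (rho 0.852), across genes, which are not independent replicates. A total of 974 windows passed in both comparisons and 973 of them had the same direction, with 668 higher and 305 lower where independent lists would share 282 and 54.7. In the WT libraries alone r was 0.616. No control of naked DNA, which would show unequal mapping of reads to the genomes, was analysed here.

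**Figure D4:**
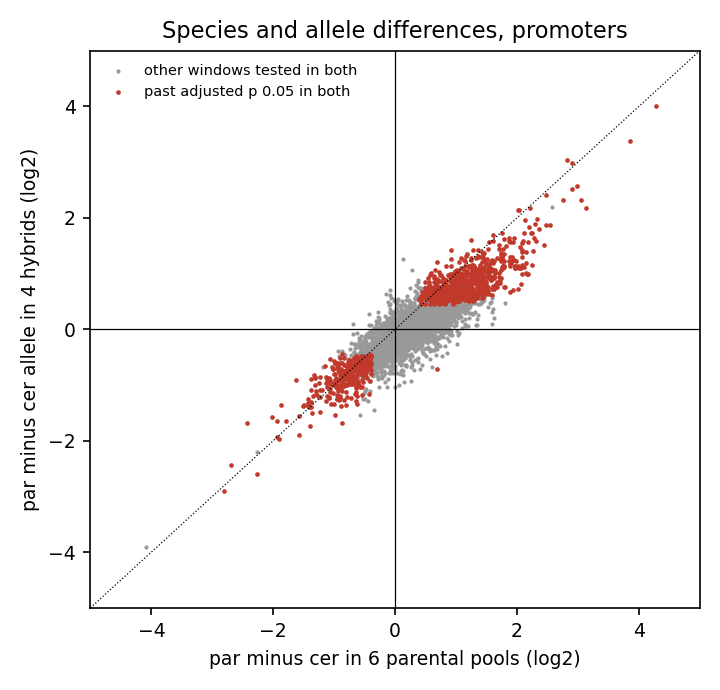
Log2 difference of promoter density, S. paradoxus over S. cerevisiae, between alleles of the hybrid against that between the parental species, for 3602 windows. Red points are the 974 windows past adjusted p 0.05 in both, of which 973 lie on the same side of 0 on both axes.

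The part of the species difference that was not seen between alleles was tested last, since it would mark factors that differ between the species' nuclei. CYC1, the cytochrome c gene, had the smallest p among upward shifts, at 0.99 ± 0.28 (limma, adjusted p 0.11). MRPL15 stood at −1.63 ± 0.33 and YMR265C at −1.30 ± 0.26 (adjusted p 0.078 each), GCR1, the activator of glycolysis genes, at −1.36, and RPS6A at −1.35 ± 0.30 (adjusted p 0.10). YMR265C, GCR1 and RPS6A lie where the S. cerevisiae signal of the gcn5 hybrid was raised, which lowers their values here. By limma 0 of 3687 windows passed and 704 had an unadjusted p under 0.05. With the species difference also paired by genotype, a fit chosen after the data were examined, 1 rose and 90 fell around a median of −0.35 for all windows in the fit without pairing, so the count of 0 rests on the model. Ribosomal protein genes stood lower as a list, at −0.68 against −0.35 (camera, adjusted p 0.000296; adjusted p = 0.823 with an estimated correlation), with 0 of 64 passing over all genes and 0 rises and 23 falls adjusted over the list alone. Without the htz1 pool, the isw1 pool and the gcn5 hybrid 2, 64 and 1 windows passed.

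Ribosomal protein genes did not pass in bre1 in S. paradoxus, in rad6, for the hybrid in S. paradoxus or between species or alleles, and no other preset list passed camera in any further comparison. Genes of the cell cycle and of mating came closest, both in bre1 in S. cerevisiae (adjusted p 0.0544 each), followed by histone genes in isw1 in S. paradoxus (adjusted p 0.0602), glycolysis genes in gcn5 in S. cerevisiae (adjusted p 0.0743) and meiosis genes in htz1 in S. cerevisiae (adjusted p 0.0822). For genes of the cell wall and of phosphate uptake the smallest adjusted p values were 0.133 and 0.161. For ergosterol synthesis, respiration and galactose use they were 0.217, 0.217 and 0.263. Genes near chromosome ends reached 0.225. The smallest values were 0.293 for the proteasome, for amino acid synthesis and for chromatin remodelling, 0.310 for hexose transport, 0.323 for the stress response and 0.581 for the mitochondrial ribosome.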

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

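The tests of the difference between genomes, of read assignment, of depth and of the steps along chromosomes were all chosen after the results were seen.

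Mutant effects on promoters were compared between the genomes, because each regulator was deleted in both species. The S. paradoxus effect minus the S. cerevisiae effect passed limma at 1 window of 3571 in htz1, 1 in isw1, 2 in gcn5, 10 in bre1 and 53 in rad6, with 196, 397, 656, 552 and 747 at an unadjusted p under 0.05. SAM4, a gene of methionine recycling, passed in every mutant, at −4.51, −4.66, −5.42, −4.96 and −5.08. Over the 900 bp downstream of the start codon, its S. paradoxus density was 1.69 to 1.81 in the WT libraries and at most 0.00798 in the mutants. This split parts WT from all mutants rather than one deletion from another. In gcn5 the other window was LDB17, at −2.57 (limma, adjusted p 0.0355). In bre1 the sterol transport gene YSP2 differed by 2.64, the vesicle fusion gene TLG1 by 2.99 and CBP4 by 2.95, all emptied in S. cerevisiae, and YMR265C differed by −2.58. In rad6 the windows included those of SOL4, of sugar phosphate metabolism, POL12, a subunit of DNA polymerase, and the pyruvate decarboxylase gene PDC5. With median-ratio scaling 1, 1, 7, 51 and 14 windows passed and relative to 41 neighbouring genes 1, 1, 30, 51 and 159. Bre1 and rad6 have 1 library each.

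Genes of chromosomes XIV, XV and XVI carried more S. cerevisiae signal in the gcn5 hybrid than in any other library, and 5 of them on chromosome XIV, RPD3, MDJ2, EGT2, PFA3 and FIG4, were empty in both genomes elsewhere. A gain of chromosomes would lift a gene by no more than the 1.52-fold of its part of the gene order. Yet these genes stood at least 8.69-fold above the median of the other libraries (densities 0.382 to 0.768, against at most 0.117). This argues against a gain alone at these genes. They are close neighbours that share reads, so they count as 1 place rather than 5 cases. Reads assigned to the genomes by another rule over part of this table may explain the steps. All 5 such genes on chromosome XIV held signal here and EHD3, a like gene on chromosome IV, stayed empty. A comparison of 1 place with 1 gene cannot settle this. An altered chromosome set together with another rule was not tested.

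Mutants sharing no library correlated across genes at a mean r of 0.235 and 0.293 in S. cerevisiae and S. paradoxus, and at 0.217 and 0.276 without ribosomal protein genes. Some genes, many of them duplicated, held positions that parted WT from all mutants, as at TDH3. Its S. cerevisiae density over the 900 bp downstream of the start codon was 0.105 to 0.116 in WT and 1.46 to 3.39 in the mutants. Other read assignment in the WT tables could give this, but its cause was not tested. Without the 58 genes that hold such positions, r was 0.230 and 0.267, so the component does not rest on these genes alone. Smaller shifts at other genes were not removed, which leaves other read assignment open. With the mutants thinned to the depth of the WT library of the same background and genome (means of 20 random draws), r was 0.183 and 0.247. The lower depth of the WT libraries therefore cannot carry the whole component. Another extent of MNase digestion in WT could raise many promoters together, and 11 of 16 depletion values lay above WT, which leaves it open. A shared response of promoters to losing a chromatin regulator was not tested. HO was empty in the S. cerevisiae genome of the WT hybrid but filled in every mutant hybrid. These hybrids therefore differ by more than the deleted regulator, and whether that bears on the component was not tested.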

How the results depend on the processing

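Array weights, scaling by 41 neighbouring genes, pseudocounts of 1 and 16, the pairing of the interaction by genotype and the fits without the genes that part WT from the mutants were chosen after the results were seen. Counts are promoter windows past adjusted p 0.05 in limma, and unless said otherwise the cause was not tested. Of the results recomputed under alternatives, 265 stayed within 1.5 times or within their spread, 89 moved and 1 reversed. Pseudocounts, no filter on low values, a log2 change of at least 0.5, smoothing SDs of 10 and 30 bp, a nucleosome-sized window at the lowest point of the profile and 8 libraries alone moved none.

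Nucleosome spacing in isw1 reversed to 1.75 bp by autocorrelation in coding sequences, where htz1 and gcn5 stood at 2.5 and 2.75 bp. Aligned on the start codon, rad6 stood at −0.1 bp. Of the gene lists, 0 passed camera with an estimated correlation (12 with the preset one, all listed in the report).

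A 150 bp window gave 27 windows in htz1 and 43 in isw1 in S. cerevisiae, 15 in htz1 in S. paradoxus and 3 for the hybrid in S. cerevisiae. A 300 bp window gave 133, 317 and 3 for htz1, isw1 and rad6 in S. cerevisiae, 48 for htz1 in S. paradoxus, 317 and 1 for the hybrid in S. cerevisiae and S. paradoxus, and 38 for the interaction. Median-ratio scaling gave 21, 112 and 1 for htz1, isw1 and the hybrid in S. cerevisiae, and 2 and 608 for htz1 and rad6 in S. paradoxus. Relative to the gene body, rad6 and the hybrid in S. cerevisiae had 14 and 292, htz1, bre1 and rad6 in S. paradoxus 13, 191 and 601, and the interaction 1.

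Array weights gave 272 for gcn5 in S. cerevisiae, 57, 175 and 22 for htz1, gcn5 and the hybrid in S. paradoxus, and 113 for the interaction. Scaling by 41 neighbouring genes gave 32 and 66 for htz1 and the hybrid in S. cerevisiae, 11 for htz1 in S. paradoxus and 1 for the interaction. Without the genes whose reads part WT from mutants, htz1 in S. paradoxus had 13, with fewer genes tested. Without the replicate block, the pairing of libraries by genotype or by genome, the hybrid comparison in S. cerevisiae had 0 windows by limma (400 at an unadjusted p under 0.05, against 802 with the block) and the alleles 662; the other 3 comparisons with a block stayed within 1.5 times. Paired by genotype as well as by library, the interaction had 91 windows, 90 of them falls, against 0 without this pairing.

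Leaving out each library in turn gave 0 to 112 windows in htz1, 75 to 197 in isw1, 15 to 490 in gcn5, 271 to 460 in bre1 and 0 to 52 in rad6 in S. cerevisiae, and 1 to 189, 87 to 805 and 190 to 667 for htz1, isw1 and gcn5 in S. paradoxus. It gave 0 to 298 and 0 to 17 for the hybrid in S. cerevisiae and S. paradoxus and 0 to 64 for the interaction. Bre1 (261 to 408) and rad6 (801 to 1194) in S. paradoxus, the species (1527 to 1900) and the alleles (835 to 1291) stayed within 1.5 times. Without its own library bre1 or rad6 has no value. Count tools with their size factors and a shift of reads were not run, because the table holds no counts. Depth limits the WT pool most, at a median of 14.8 reads per S. cerevisiae promoter.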

Other observations

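The tests of mating genes and the counts over other splits of the libraries were all chosen after the results were seen.

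Of the a-specific genes, 3 of 4 (AGA2, BAR1 and STE2 but not ASG7) had a changed 100 bp window in the S. cerevisiae genome between pools and hybrids, against 178 of 3742 other genes (Fisher's exact one-sided p 0.000428), and 0 of 4 in S. paradoxus by limma. Of the alpha-specific genes, 0 of 3 had one in S. cerevisiae and 3 of 3 (MF(ALPHA)1, MF(ALPHA)2 and STE3) in S. paradoxus, against 10 of 3740 (exact p 3.27e-08), while a test of these 6 genes by class and genome can give no exact p under 0.1. The label of the parental S. cerevisiae strain names a diploid that keeps 1 intact copy of MET17. That copy would give 946 estimated reads in 800 bp inside the gene over the 6 pools, yet 0 were found there. From 1000 to 100 bp upstream of the start codon 317 were found, a stretch for which no expected number was computed. MET17 was empty in the S. cerevisiae genome of all 10 libraries, hybrids included. Reads of this gene that were not mapped would look the same, so the 0 cannot decide whether that diploid was in the pools. Haploid parents of opposite mating type against a diploid hybrid remain a candidate explanation. Of the 7 genes, 6 changed in the genome that this explanation names and 0 in the other, with passing windows upward at 5 and downward at MF(ALPHA)2. The explanation was framed after these values were seen, so the match is no test of it. Whether the strains were haploid cannot be read from these tables directly, and MET17 held 103% to 175% of the mean density in the S. paradoxus genome.

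Regrouping the libraries tested whether chance could give as many changed promoters. For hybrids against pools in S. cerevisiae, 1 of 35 splits of the 8 libraries gave at least the 139 windows of the real one (highest other 73, with 3 splits that could not be fitted). The libraries are paired by genotype, though, and only 8 splits part every pair, the highest other of these giving 29. So few cannot give a share under 0.05, which leaves chance open. In S. paradoxus 32 of 35 splits gave as many as the real 0, with 393 windows at an unadjusted p under 0.05 in limma, and the highest other gave 2, but a real count of 0 leaves nothing for the splits to test. For the species in the pools 1 of 32 splits gave the real 1828, the highest other giving 1. That share, 0.0313, is under 0.05 but is the smallest that 32 splits can give. In the other splits the species difference itself adds to the spread, which lowers their counts. Unequal mapping of reads would repeat in every pool, so the splits do not test it. The alleles in the hybrids have 8 splits, too few for a share under 0.05; 1 gave as many as the real 1226 and the highest other gave 0 by limma, with 1602 at an unadjusted p under 0.05 in the real one. For the interaction 35 of 35 splits gave as many as the real 0 (704 at an unadjusted p under 0.05), and the highest other gave 15, which tests nothing for the same reason; paired by genotype, the real count was 91.

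Genes on chromosome XV stood 1.42-fold above the other libraries in the S. paradoxus genome of the htz1 hybrid (249 genes). In the S. cerevisiae genome of this hybrid, the 89 genes from ATP20 on chromosome XVI stood at a median log2 of −0.575 against the other libraries. TEF1 is an elongation factor gene with a near-identical copy. Over the 900 bp downstream of the start codon it held a S. paradoxus density of 0.132 to 0.145 in the WT libraries and 1.32 to 3.30 in the mutants. HXT15, of the hexose transporter family, held 3.15 to 3.37 in WT and 0.0994 to 0.256 in the mutants in S. cerevisiae over the same stretch.

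Outside the 200 bp upstream of the start codon, genes with at least 1 changed window of 100 bp numbered 234, 893, 2674, 1078 and 36 for htz1, isw1, gcn5, bre1 and rad6 in S. cerevisiae, and 210, 2245, 2430, 491 and 2020 in S. paradoxus. Those of gcn5 in S. cerevisiae include the chromosomes raised in its hybrid. The species differed at 3597 genes and the alleles at 2932, the hybrid comparison gave 121 and 13 genes, and the interaction without pairing gave 0 by limma, with 704 promoter windows at an unadjusted p under 0.05.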
